A study of Mus musculus with 2 samples.

How the data were processed

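DNase-seq was performed on heart tissue of male B6CASTF1/J mice aged 10 days in 2 biological replicates, and the libraries are named replicate 1 and replicate 2 after the labels. Reads were not used. Per the deposited README files, each library was processed on its own, without pooling, and all files are on the mouse build mm10 and derive from the library's filtered alignment. The aligner, the peak caller, the footprint caller and their thresholds are not given in the sources used here.

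For each library the authors deposited 2 peak lists of different length, an FDR list of the cut rate and a list of footprints. The peak lists give a signal per peak, per the deposited narrowPeak layout. The deposited signal values were whole multiples of a small step in each library (100% of peaks, within 0.02 steps), as a cut count divided by library depth would be. The step was 0.00424 in replicate 1 and 0.00453 in replicate 2. This reading of the step is an inference from the values, and no sequencing depth is given in the sources used here. Signal values are the authors' own and were used to rank and describe peaks. Their ratio between libraries describes 2 separately normalized lists. The deposited FDR values (adjusted p-values of the local cut rate) were listed only up to 0.05. At that level they covered 75.8 Mb in replicate 1 and 63.9 Mb in replicate 2, with 52.2 Mb in common. Of the bases of the shorter peak lists, 98.7% and 99.4% lay at an FDR of at most 0.001. The score column of the deposited footprints held the same constant in every row, so footprints could not be ranked.

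The shorter peak list of each library was the main list, with 131374 and 137965 peaks, and the longer list, with 205077 and 211478 peaks, was an alternative. Chromosomes 1 to 19, X and Y of GRCm38.p6 were used with GENCODE release M21, and every deposited coordinate lay within these chromosomes. Overlap required at least 1 bp. Chance overlap and placement came from 20 shuffles of positions within chromosomes. A promoter peak lay within 500 bp of any annotated start site, and other peaks were placed by their centre in exons, introns or intergenic sequence. Distal peaks lay outside 500 bp of every annotated start site and were counted for a gene if their centre was within 50 kb of its most 5' start site. A peak near the start sites of 2 genes counted for both.

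A set of 18 gene lists was fixed before the data were examined, covering cardiomyocyte programmes, other cell types the tissue can hold, other tissues, cell cycle and housekeeping genes, and 314 of 315 list entries matched the annotation. Ahsp, of the erythroid list, did not. For each list the percent of genes with a promoter peak and the mean number of distal peaks, averaged over both libraries, were compared with 10000 random lists of the same size drawn from 21911 protein-coding genes. Random lists for distal peaks were matched on gene length in 10 bins. Drawing random lists permutes list membership among genes, so the test is a permutation test over genes. Two-sided p-values were adjusted by the Benjamini-Hochberg method over 18 lists, with 0.05 as the threshold. Genes are not independent replicates, and these p-values describe how the lists stand among genes of these 2 libraries, not differences between animals. With a single group no test between groups was possible. Values are given as mean ± SD over 2 libraries, or as both values.

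A set of 28 consensus sequences, also fixed before the data were examined, was matched on both strands. The number of matches centred in footprints per base was divided by that in the rest of the peaks that hold footprints. Each consensus was compared with 10 shuffled versions of itself, and a ratio needed at least 10 matches in the background. Consensus matching does not show which protein was bound. Footprint calling depends on cut density and on the sequence preference of DNase I, which were not corrected here.

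Genes named in the text followed a rule fixed before the data were examined. For each list, up to 4 members with the highest mean promoter signal and a promoter peak in both libraries were named, and up to 3 members without a promoter peak in either, in alphabetical order. Genome-wide, the 10 strongest promoters, the 10 strongest distal peaks and the 10 genes with most distal peaks were named, each by the lower of its 2 values, and the 5 strongest unshared peaks of each library. Some of the genes this rule names are not reported here.

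The list test was tested on simulated data with 20000 genes and lists of 20 genes. Of 200 promoter lists without an effect, 5% had p below 0.05, and of 200 lists raised from 67% to 95%, 92.5% did. Of 200 length-matched distal lists, 4.5% without an effect and 100% with a 2-fold excess had p below 0.05. Lists without an effect were drawn at random, and simulated distal counts were independent between genes of a length class. The simulation therefore does not cover real lists whose genes share windows. A planted motif ratio of 10 was recovered as 11.2. Alternatives covered the peak list, the stronger 50% of peaks, equal numbers of peaks, each replicate left out, overlap rules, promoter and distal windows, start sites, overlapping gene windows, random lists and footprint backgrounds. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1.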

Results

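Open chromatin was mapped by DNase-seq in the heart of 10-day-old male B6CASTF1/J mice. These animals are first-generation hybrids of C57BL/6J and CAST/EiJ. DNase I cuts DNA where nucleosomes are displaced, so that clusters of cuts mark promoters, enhancers and insulators. The labels give a single group with 2 biological replicates, and no treatment, age series or second tissue. The replicates are taken here as hearts of separate animals, which the labels do not state. The comparisons open to this design are therefore between the 2 hearts, between fixed gene lists and random gene lists, and between protected and unprotected bases inside peaks. Replicate 1 held 131374 peaks covering 28.7 Mb, which was 1.08% of the assembled chromosomes. Replicate 2 held 137965 peaks covering 25.1 Mb, or 0.947%. The median peak was 200 bp wide in replicate 1 and 180 bp wide in replicate 2. A median peak rested on 185 counting steps in replicate 1 and 248 in replicate 2, which, if each step is 1 cut, corresponds to a Poisson error of 7.35% and 6.35%, counting error only.

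The 2 hearts shared most of their accessible regions, and sharing was nearly complete among the strong ones. Of the peaks of replicate 1, 79.3% overlapped a peak of replicate 2, against 2.24% for positions shuffled within chromosomes. In the other direction the share was 76.3%, against 2.10%. Among the strongest 10% of peaks, 99.8% of those of replicate 1 and 99.2% of those of replicate 2 were found in the other heart, and among the weakest 10% the shares were 34.3% and 43.2%. When the other animal's longer peak list was searched, 89.0% and 89.1% of the peaks were found. Across the 104136 shared peaks the rank correlation of peak signal was 0.90 (Spearman's rho, across peaks, which are not independent replicates). Peak signal was higher in replicate 2 at 86.2% of shared peaks. The median log2 ratio of replicate 2 over replicate 1 was 0.99 at promoter peaks and 0.59 at distal peaks. It rose from 0.29 in the weakest 10% of shared peaks to 1.40 in the strongest 10%. No peak had the same position and signal in both lists, so the files were taken as 2 different libraries.

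**Figure D1:**
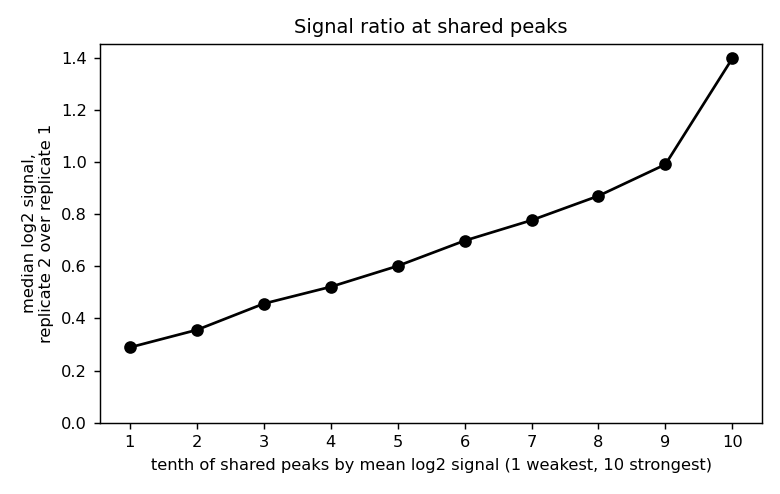
Median log2 ratio of peak signal, replicate 2 over replicate 1 (y axis), at shared peaks divided into 10 equal classes by mean log2 signal (x axis, 1 weakest to 10 strongest). Each point is a median over about 10414 peaks, and the medians rise from 0.29 to 1.40.

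Accessible regions lay at promoters far more often than their positions would give by chance. Promoter peaks, within 500 bp of an annotated start site, made up 23.3% ± 0.235 of all peaks (SD, n = 2), against 4.04% for shuffled positions. Exons held 5.90% ± 0.360 (chance 3.77%), introns 39.5% ± 0.721 (chance 41.5%) and intergenic sequence 31.3% ± 0.846 (chance 50.7%). Promoters held 70.0% of the strongest 10% of peaks. A promoter peak was present at 14752 of 21911 protein-coding genes in replicate 1 (67.3%) and at 14978 in replicate 2 (68.4%). The 2 hearts had 14506 of these genes in common, and 6687 genes had no promoter peak in either. The promoter share depended on the definition, with 15.7% for a distance of 100 bp, 29.1% for 1000 bp and 33.5% among the stronger 50% of peaks.

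Almost all promoters of the contractile and metabolic programme of the cardiomyocyte had a peak. Here and below, a promoter is called open where it had a peak of the shorter list, unless stated, whatever its signal. All 22 genes of fatty acid oxidation and cardiac energy metabolism had a promoter peak in both hearts. Of the 22 sarcomere genes, 21 had a promoter peak in replicate 1 and 22 in replicate 2. For the 21 genes of calcium handling and conduction these numbers were 20 and 21, and for the 20 cardiac transcription factors they were 19 and 19. As a mean of both hearts, the shares were 100% ± 0 for energy metabolism, 97.7% ± 3.21 for the sarcomere, 97.6% ± 3.37 for calcium handling and 95% ± 0 for transcription factors, while random lists averaged 67.8%. All 4 lists stood above the random lists, with adjusted permutation p = 0.0012 for sarcomere and for energy metabolism, 0.0018 for calcium handling and 0.0108 for transcription factors. These are two-sided permutation p-values from 10000 random lists, adjusted by the Benjamini-Hochberg method over 18 lists. Both libraries showed the direction in each of the 4 lists. Among promoters with a peak, the median signal was 2.23 and 5.56 for sarcomere genes. It was 1.75 and 3.79 for calcium handling and 2.78 and 9.22 for transcription factors. These values lay below the 4.29 and 9.88 of all protein-coding genes with a promoter peak, while energy metabolism lay above (5.17 and 12.9). The strongest sarcomere promoters were those of Myom1, an M-band protein (signal 9.79 in replicate 1 and 37.2 in replicate 2), Tpm1, which encodes tropomyosin (9.09 and 31.03), Myl4, the atrial essential light chain (12.9 and 22.6), and Actn2, the Z-disc actinin (3.68 and 12.4). The Myom1 peak also lay at a start site of Myl12a and the Myl4 peak at a start site of Cdc27, so neither can be assigned to the sarcomere gene alone. The Tpm1 value belonged to an alternative start site, and at the most 5' one the signal was 3.88 and 15.2. Among calcium handling genes the strongest were Camk2d (9.51 and 26.6), the potassium channel genes Kcnj2 (5.18 and 17.1) and Kcnh2 (3.74 and 15.3), and Atp2a2, the calcium pump of the sarcoplasmic reticulum (4.64 and 15.9). In energy metabolism they were Acadm (8.70 and 30.2) and Acadl (8.93 and 20.7), dehydrogenases of fatty acid oxidation, Slc25a4, the mitochondrial ADP/ATP carrier (8.14 and 26.8), and the glucose transporter gene Slc2a4 (7.18 and 22.7). Esrra (14.95 and 48.2), Tead1 (8.91 and 24.1), Mef2a (8.38 and 24.1) and Srf (7.15 and 20.6) led the transcription factors. Hand1, on chromosome 11 at 57828705 to 57832818 in GRCm38, was the only member with no promoter peak in either heart. Against random lists matched on promoter GC content the transcription factor list was no longer past the threshold (adjusted permutation p = 0.104, range 0.00206 to 0.104 over 10 alternatives). The calcium handling list was not past it with a single start site per gene (0.0720), with a window of 100 bp (0.0800) or with the stronger 50% of peaks (0.0818), where its adjusted permutation p over 10 alternatives began at 0.00072.

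**Figure D2:**
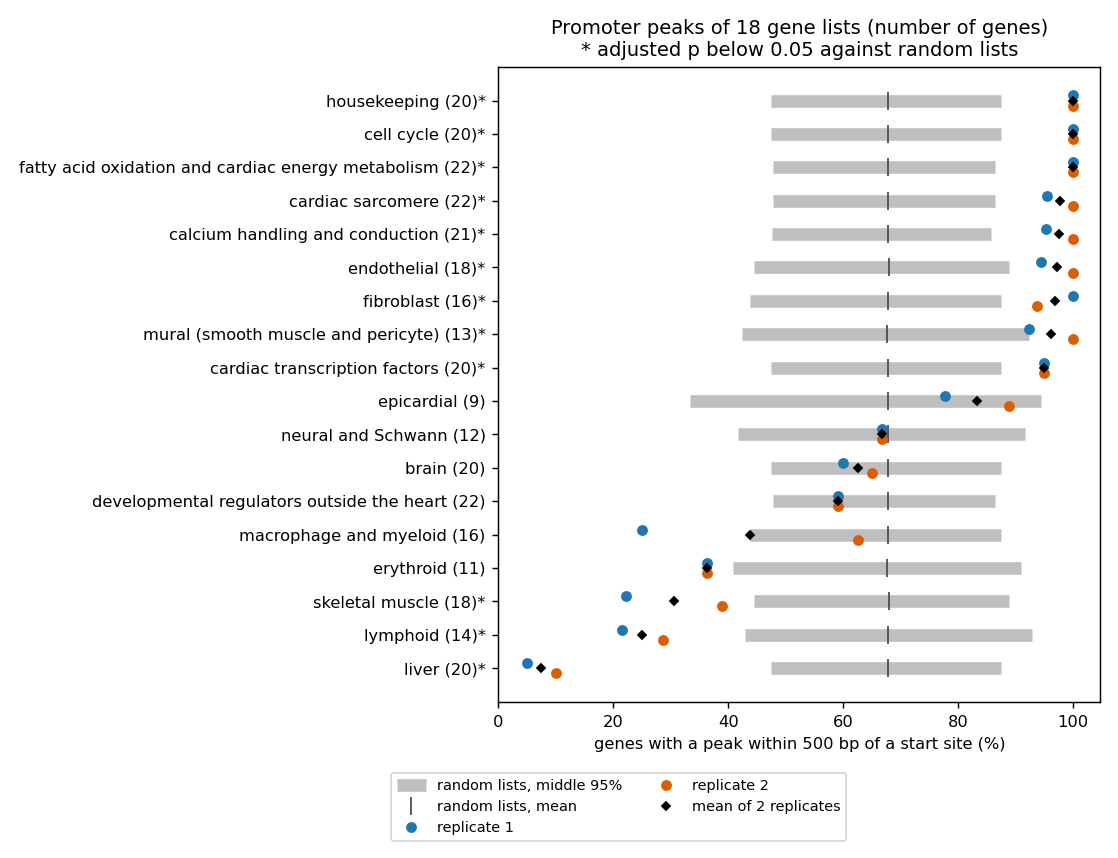
Percent of genes with a peak within 500 bp of a start site (x axis) for 18 gene lists (y axis, number of genes in parentheses). Circles are the 2 replicates, diamonds their mean, and grey bars the middle 95% of 10000 random lists. Liver genes lie lowest at 7.5%, and energy metabolism, cell cycle and housekeeping genes at 100%.

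Promoters of fibroblasts, endothelial cells and mural cells were open as well. All 16 fibroblast genes had a promoter peak in replicate 1 and 15 in replicate 2. Endothelial genes had 17 and 18 of 18, and mural genes, expressed in smooth muscle and pericytes, had 12 and 13 of 13. The mean shares of 96.9% ± 4.42, 97.2% ± 3.93 and 96.2% ± 5.44 lay above random lists in both libraries (adjusted permutation p = 0.0108, 0.0056 and 0.0198). Their median signals were 1.95 and 4.997 for fibroblast, 1.54 and 3.03 for endothelial and 1.62 and 4.49 for mural genes. All lay below the median of all genes with a promoter peak (4.29 and 9.88). Named fibroblast promoters were Fn1, which encodes fibronectin (5.09 and 17.3), Col1a1, the alpha 1 chain of type I collagen (6.08 and 9.08), Pdgfra (3.93 and 10.8) and Vim (4.41 and 10.1). Vwf, which encodes von Willebrand factor (5.34 and 7.94), Esam (2.57 and 7.14), Eng (2.46 and 6.98) and the VEGF receptor gene Kdr (1.956 and 5.06) led the endothelial list. Smtn (6.09 and 13.9), Mylk (3.51 and 10.3), Myh11, the smooth muscle myosin heavy chain (3.33 and 7.29), and Cspg4 (1.98 and 6.77) led the mural list, and the Cspg4 peak also lay at a start site of Odf3l1. The Vwf and Smtn peaks lay at start sites other than the most 5' one, where neither gene had a peak. The values of Pdgfra and Col1a1 also belonged to alternative start sites, and at the most 5' one the signal was 1.04 and 1.36 for Pdgfra and 2.32 and 8.05 for Col1a1. Epicardial genes had 7 and 8 of 9 promoters open, led by Tbx18 (3.37 and 10.3), Aldh1a2 (2.85 and 6.42), Sema3d (2.36 and 5.24) and Wt1 (1.13 and 2.86), while Upk3b had none. Their mean of 83.3% ± 7.86 did not pass the test (adjusted permutation p = 0.430). The fibroblast call was lost without replicate 1 (adjusted permutation p = 0.0567) and the mural call without replicate 2 (0.106). With a single start site per gene the fibroblast, endothelial and mural lists no longer passed (0.0958, 0.265 and 0.0720), nor did the mural list with the stronger 50% of peaks (0.116), and over 10 alternatives the adjusted permutation p-values began at 0.00072, 0.00206 and 0.0115 for the 3 lists.

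Lymphoid promoters stood below random lists, with 3 of 14 genes open in replicate 1 and 4 in replicate 2 (mean 25% ± 5.05, lower in both libraries, adjusted permutation p = 0.0045). Cd3d and Cd3e, which encode T cell surface proteins, had no promoter peak in either heart. The peaks credited to Pax5 (3.96 and 10.5), Lck (4.13 and 9.69) and Cd2 (2.70 and 4.46) all lay at alternative start sites. At the most 5' start site Lck and Cd2 had no peak in either heart, and Pax5 had one of signal 0.263 in replicate 1 alone. Erythroid genes had 4 of 11 promoters open in each heart (36.4% ± 0), which was lower in both libraries and did not pass the adjusted test (adjusted permutation p = 0.0687). A further gene of this list, Ahsp, had no match in the annotation. Among the open ones were Epor, the erythropoietin receptor gene (1.66 and 3.82), Tal1 (1.32 and 2.29) and Slc4a1 (0.581 and 1.72, at an alternative start site), while Alas2, Gata1 and the globin gene Hba-a1 had none. With the longer peak list the erythroid list passed the test (adjusted permutation p = 0.0327, range 0.0327 to 0.189 over 10 alternatives). Macrophage and myeloid genes were the list on which the 2 hearts differed most, with 4 of 16 promoters open in replicate 1 and 10 in replicate 2 (25% and 62.5%). Cd68 (0.900 and 1.31), Lyz2, which encodes lysozyme (0.628 and 0.670), and Cd14 (0.696 and 0.552) were open in both, and Aif1, Csf1r and Itgam in neither. With the longer peak lists, 11 of 16 promoters had a peak in replicate 1 and 15 in replicate 2. A missing peak in the shorter list therefore does not show a closed promoter. The macrophage and myeloid list did not pass the test (mean 43.8% ± 26.5, adjusted permutation p = 0.0841). Taken from replicate 1 alone, that is without replicate 2, it lay below random lists (adjusted permutation p = 0.0027), and so it did among the stronger 50% of peaks (6.25%, adjusted permutation p = 0.0006, range 0.0006 to 0.896 over 10 alternatives). Neural and Schwann genes had 8 of 12 promoters open in each heart (66.7% ± 0, adjusted permutation p = 1). Among the open ones were Elavl4 (1.08 and 1.73), Tubb3 (0.7002 and 1.90) and Mbp (0.611 and 1.92). Dbh and Sox10 had no promoter peak.

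Liver and skeletal muscle promoters mostly had no peak, while brain genes and developmental regulators lay within the range of random lists. Of 20 liver genes, 1 had a promoter peak in replicate 1 and 2 had one in replicate 2 (mean 7.5% ± 3.54, lower in both libraries, adjusted permutation p = 0.0012). Ahsg, Alb, the albumin gene, and Apoa1 had none, and the Apoh peak, present in both hearts (2.36 and 4.83), also lay at a start site of Prkca. Of 18 skeletal muscle genes, 4 and 7 had a promoter peak (mean 30.6% ± 11.8, lower in both libraries, adjusted permutation p = 0.0031). The myogenic factor genes Myf5 and Myf6 and the fast muscle calcium pump gene Atp2a1 had none. Mylpf, a fast light chain gene, stood out with 5.23 and 20.2, at a peak shared with a start site of Tbc1d10b, ahead of Ryr1 (0.862 and 0.905), Actn3 (0.547 and 1.04) and Acta1 (0.399 and 0.860). This list no longer passed with a window of 1000 bp (adjusted permutation p = 0.204, range 0.0006 to 0.204 over 10 alternatives). Brain genes had 12 and 13 of 20 promoters open (mean 62.5% ± 3.54, adjusted permutation p = 0.697), led by Camk2a (3.24 and 7.60, at an alternative start site), Gfap (3.64 and 6.28), Dlx1 (2.44 and 4.13, at an alternative start site) and the NMDA receptor gene Grin1 (1.66 and 3.29), with none at Emx1 or Gad1. Developmental regulators outside the heart had 13 of 22 promoters open in each heart (59.1% ± 0, adjusted permutation p = 0.508). Lhx2 (1.93 and 4.88, at an alternative start site), Hoxc10 (1.43 and 2.43) and Pax6 (1.16 and 2.40, at an alternative start site) were among the strongest, and Cdx2, Hoxa13 and Hoxb1 had none. With the longer peak lists, 14 and 18 of the 20 brain promoters had a peak, and 15 and 17 of the 22 developmental ones. At the most 5' start site Camk2a and Pax6 had no peak in either heart, and Dlx1 and Lhx2 had one in replicate 1 alone, of signal 0.530 and 0.412. Against random lists matched on promoter GC content, which averaged 85.6%, the developmental list was lower (adjusted permutation p = 0.0012). Among the stronger 50% of peaks the brain list (27.5%, adjusted permutation p = 0.0052) and the developmental list (31.8%, adjusted permutation p = 0.0147) were also lower than random lists. Over 10 alternatives their adjusted permutation p-values reached 1.

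Genes of dividing cells and of general upkeep were open throughout, with 20 of 20 cell cycle genes and 20 of 20 housekeeping genes in both hearts (100% ± 0, adjusted permutation p = 0.0030 for each list, higher in both libraries). Ccne1 (11.4 and 35.1) and Ccna2 (9.31 and 30.2), which encode cyclins, the replication helicase gene Mcm5 (13.1 and 32.8) and Cdk1 (10.1 and 25.4) led the cell cycle list. Rplp0 (15.9 and 39.2), Vcp (10.1 and 34.3), Actb (11 and 32.4) and Psmb2 (11.9 and 30.5) led the housekeeping list, where the Actb value belonged to an alternative start site (7.44 and 25.1 at the most 5' one). Of the 20 housekeeping promoters, 9 in replicate 1 and 7 in replicate 2 were among the strongest 10% of all genes, against 3 and 2 of the 22 sarcomere promoters. With GC-matched random lists neither list passed (adjusted permutation p = 0.0753 for both, range 0.0006 to 0.0753 over 10 alternatives).

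Sarcomere genes and cardiac transcription factor genes had the highest mean numbers of distal peaks among the 18 lists. Within 50 kb of the start site, sarcomere genes had 17.6 ± 0.514 distal peaks per gene (SD, n = 2), against 5.89 for random lists matched on gene length, a 2.98-fold excess. Cardiac transcription factors had 13.2 ± 1.34 against 5.90 and calcium handling genes 10.5 ± 1.41 against 5.64. Each of these 3 lists reached adjusted permutation p = 0.0012, from the smallest p that 10000 random lists can give (0.0002), and was higher in both libraries. Energy metabolism genes had 10.1 ± 0, against 6.04 (adjusted permutation p = 0.0094). Lists of other cell types of the heart were also higher in both libraries, with 10.5 ± 0.982 for endothelial genes (random 5.74, adjusted permutation p = 0.0054), 10.3 ± 1.69 for mural genes (random 5.86, adjusted permutation p = 0.0226) and 10.1 ± 0.884 for fibroblast genes (random 6.11, adjusted permutation p = 0.0238). Cell cycle genes had 10.4 ± 0.601 (random 6.13, adjusted permutation p = 0.0120) and housekeeping genes 9.33 ± 0.177 (random 6.14, adjusted permutation p = 0.0496). The other 9 lists were not called, neural and Schwann genes at 9.38 (adjusted permutation p = 0.0958), macrophage and myeloid genes at 7.91 (0.221), brain genes at 7.45 (0.334), skeletal muscle genes at 7.42 (0.334), developmental regulators at 6.52 (0.645), epicardial genes at 5.56 (0.945), erythroid genes at 5.32 (0.869), lymphoid genes at 5.29 (0.775) and liver genes at 4.80 (0.394). No list was lower at an adjusted or an unadjusted p under 0.05. The fibroblast and housekeeping calls were lost without replicate 1 (adjusted permutation p = 0.102 for both), the mural call without replicate 2 (0.0592), the fibroblast and mural calls at 100 kb (0.0900 and 0.0886) and among the stronger 50% of peaks (0.0760 and 0.0562), and the cell cycle and housekeeping calls at 20 kb (0.123 for both). Over 11 alternatives the adjusted permutation p ranged from 0.0018 to 0.102 for fibroblast, 0.0048 to 0.0886 for mural, 0.0027 to 0.123 for cell cycle and 0.0300 to 0.123 for housekeeping genes.

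**Figure D3:**
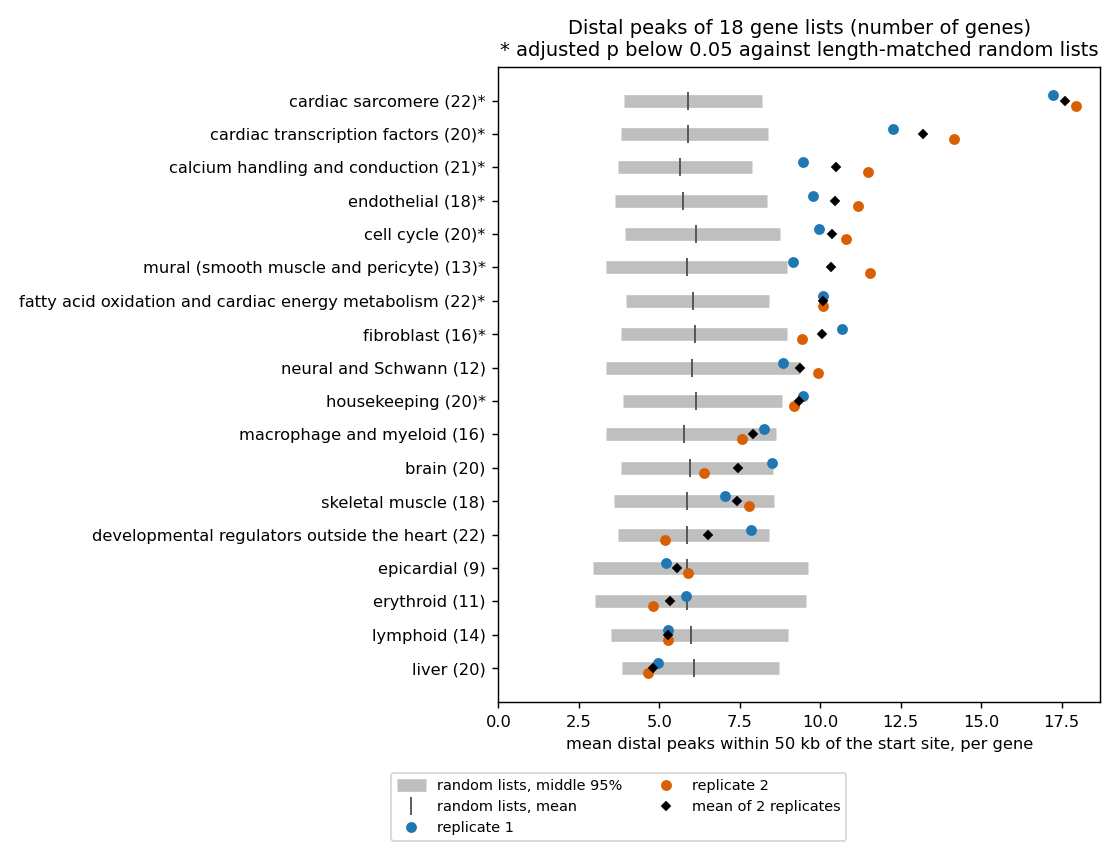
Mean number of distal peaks per gene within 50 kb of the start site (x axis) for 18 gene lists (y axis, number of genes in parentheses). Circles are the 2 replicates, diamonds their mean, and grey bars the middle 95% of 10000 random lists matched on gene length. Sarcomere genes lie highest, at 17.6 distal peaks.

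Genome-wide, the 10 genes with the most distal peaks included the nuclear receptor genes Thra and Rara, both on chromosome 11, and a neighbour of a troponin locus. No gene group was tested among these genes. Bahcc1 had 51 distal peaks in replicate 1 and 54 in replicate 2, Ptgis, the prostacyclin synthase gene, 45 and 46, Thra, the thyroid hormone receptor alpha gene, 54 and 45, and Rara, a retinoic acid receptor gene, 44 and 52. Ddit4 had 39 and 40, Smim24 had 37 and 43, Trim8 had 37 and 55, Gm48552 had 36 and 43, and Lad1 had 54 and 36. Smim24 and Gm48552 start close together on chromosome 10 (81393051 and 81389005), so their windows hold mostly the same peaks. The Lad1 window (chromosome 1, 135768598 to 135868598, GRCm38) also holds Tnnt2, which encodes cardiac troponin T, and Tnni1, the slow skeletal troponin I. Tnnt2, named after its values were seen, had 52 and 33 distal peaks. Among the 10 strongest promoters genome-wide was no gene of the 18 lists. The peak between Hjurp, a centromere histone chaperone gene, and Trpm8 had a signal of 36.5 in replicate 1 and 85.6 in replicate 2. It was followed by Dynlt1b (24.4 and 76.7), the shared promoter of Mplkip and Sugct (20.1 and 71.7), Nup107, a nuclear pore gene (19.7 and 64.5), Bahcc1 (19.6 and 71.04), the shared promoter of Ankrd16 and Fbh1 (19.4 and 56.9) and Eif5a (19.4 and 54.1). In the Dynlt1b peak, 53.1% of the 31-base words occurred more than once in the genome, and in the other strongest promoter peaks 0%.

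**Figure D4:**
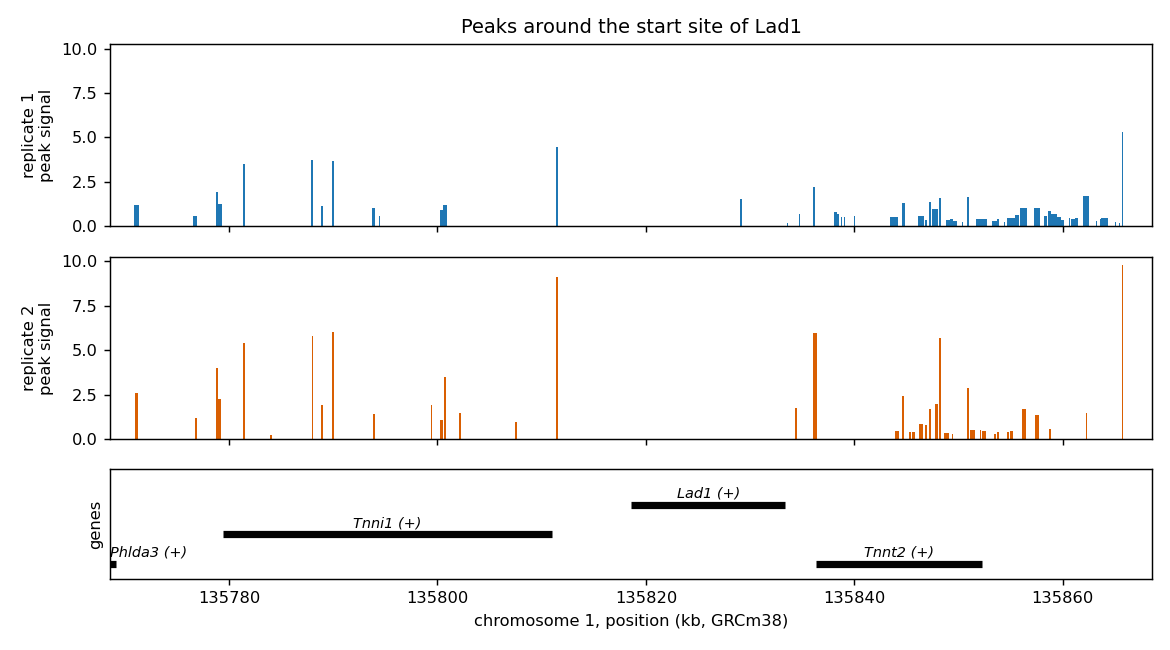
Peak signal (y axis, the same scale for both replicates) of the peaks of replicate 1 and replicate 2 within 50 kb of the start site of Lad1 on chromosome 1 (x axis, kb, GRCm38), with the protein-coding genes below (strand in parentheses). The Lad1 window held 54 distal peaks in replicate 1 and 36 in replicate 2, and those of replicate 1 crowd within and downstream of Tnnt2.

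The strongest distal peaks lay mostly in sequence present in several copies. Ranked by the lower of the 2 values, the strongest was in an exon of Lars2 (chromosome 9, 123461901 to 123462100), with a signal of 54.1 in replicate 1 and 44.0 in replicate 2. Next came an intergenic peak 21.6 kb from Igf2bp3 (chromosome 6, 49236421 to 49236620, signals 43.6 and 37.5), an exonic peak in Kpna1 (47.4 and 32.5), an intronic peak in Il31ra (37.3 and 28.9), a peak in an intron of Mid1 on the X chromosome (169997961 to 169998240, signals 19.8 and 81.2) and an intergenic peak on chromosome 3 (5860361 to 5860530, signals 37.2 and 19.02). The next 2 also lay in intronic sequence of Mid1. Signals were 17.8 and 25.8 for the peak starting at 169991321 and 17.7 and 81.2 for that ending at 169998420. The value of 81.2 came from the same peak of replicate 2 as before. An exonic peak in Cers5 (21.6 and 16.3) and an intronic peak in Jarid2 (15.9 and 19.3) completed the 10. In 8 of the 10 peaks, over 50% of the 31-base words occurred more than once in the reference, against 3 of 200 other distal peaks drawn at random. The peaks in Mid1 were among these 8 and lay close together, so the 8 are not independent cases. The Cers5 peak had none and the Jarid2 peak 37.3%.

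Peaks found in a single heart were weak as a rule. The median signal of peaks not shared was 0.378 in replicate 1 and 0.584 in replicate 2, against 0.993 and 1.52 for shared peaks. The strongest peak of replicate 2 without an overlapping peak in replicate 1 lay on chromosome 12 at 113156001 to 113156220, 0.310 kb from the start site of Tedc1, with a signal of 39.4. The next 4 lay near Gatad2b (27.7), in an intron of Sin3a (20.6), in intergenic sequence 153.8 kb from Smim15 (15.6) and in an exon of Pcgf1 (15.6). In replicate 1 the 5 strongest were near Lims1 (8.62), in an intron of Ptprs (8.11), near Tmem143 (6.96), near Ice1 (6.79) and near Tmpo (6.70). Distances to the start site were 0.037 kb for Gatad2b, 0.305 for Lims1, 0.09 for Tmem143, 0.407 for Ice1 and 0.206 for Tmpo. These peaks and the Tedc1 peak thus lay within the promoter distance of 500 bp. None of these 10 peaks overlapped a peak of the longer list of the other library. All but the Tedc1 peak had a peak of the other library within 200 bp. For 8 of these 9, every such neighbour overlapped another peak of the same library as the unshared one, the exception being the peak near Ice1.

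Footprints, the short stretches protected from DNase I inside accessible regions, carried the binding sequences of CTCF, NRF1, the cAMP response element and RFX many times more densely than the rest of the same peaks. The density of CTCF matches, the insulator protein, was 57.1 times higher in footprints than in the rest of the same peaks in replicate 1 and 42.5 times higher in replicate 2, while shuffled versions of the consensus averaged 1.73. A background taken 100 bp away could be drawn only for footprints with room for it in their peak, clear of other footprints, which held 1063 and 554 of the 11681 and 10520 CTCF matches in footprints. For these footprints the CTCF ratios were 13.02 and 7.12 with the rest of their peaks as the background and 14.3 and 9.15 with the shifted one, so the lower ratio went with the choice of footprints. The ratio was 36.8 ± 11.7 (SD, n = 2) for NRF1, 17.0 ± 1.03 for the cAMP response element, 10.4 ± 0.542 for RFX, 8.82 ± 0.175 for SP/KLF, 5.29 ± 1.61 for ETS and 3.77 ± 0.942 for YY1. For REST, the neuronal repressor, it was 65.4 ± 9.38 on 352 and 332 matches in footprints, and its shuffled versions had too few matches for a ratio. For the footprints with room for the shift, REST had 10.9 and 5.10 on 18 and 9 matches, NRF1 31.3 and 15.1, ETS 4.98 and 3.38, and YY1 2.67 and 2.29 with the rest of their peaks as the background. With the shifted background ETS had 3.97 and 2.83 and YY1 2.33 and 1.75, while REST and NRF1 had too few background matches for a ratio in either library and RFX in replicate 1. EBF/COE stood at 2.91 ± 0.542, the NEUROD E-box at 2.13 ± 0.222, the MyoD E-box at 1.84 ± 0.309 and NFY at 1.78 ± 0.288. The NEUROD consensus, CAGATGG, contains the reverse complement of the HAND consensus, CATCTG, so each NEUROD match is also a HAND match. The CTCF consensus allows CAGATGG within it as well, so these sequences are not distinct and the NEUROD ratio cannot be assigned to a neural factor. Divided by the ratios of their shuffled versions, EBF/COE fell to 1.16 and 1.45 and the MyoD E-box to 1.64 and 1.24, so neither exceeded 1.5 in both libraries, and the NEUROD E-box had 2.12 and 1.97. Of 8 heart consensus sequences, none exceeded 1.5 in both libraries, against 7 of 8 general ones, with the rest of the peaks as the background. For the footprints with room for the shift ESRR exceeded it, with the rest of their peaks (1.66 and 1.503, against 6 general ones) and with the shifted background (2.29 and 1.78, on 37 and 35 background matches, against 5, with no ratio for NRF1). On the scale relative to shuffled versions ESRR (2.36 and 2.31) and the SRF CArG box (1.85 and 1.63) exceeded 1.5 in both. MEF2 (3.31 and 1.49) and the HAND E-box (1.59 and 1.40) exceeded 1.5 on this scale in replicate 1 alone. There the SP/KLF sequence (1.73 and 1.55), NFY (2.11 and 1.79) and AP-1 (0.974 and 0.843) were below ESRR, while CTCF (34.2 and 23.7), NRF1 (24.6 and 16.6) and the cAMP response element (22.4 and 21.4) stayed far above the heart sequences. The HAND E-box had a ratio of 1.43 ± 0.211, ESRR 1.33 ± 0.157, the SRF CArG box 1.19 ± 0.249, NKX2-5 0.903 ± 0.145, TEAD 0.816 ± 0.0671, TBX 0.715 ± 0.0634 and GATA 0.516 ± 0.178. MEF2 differed most between the hearts among these, with 2.01 in replicate 1 and 0.696 in replicate 2. For footprints shared by both replicates the MEF2 ratios were 1.27 and 0.740, and with the shifted background 2.90 and 0.982. MEF2 and the SRF CArG box nevertheless exceeded all of their 10 shuffled versions in both libraries, as did 10 of the 28 consensus sequences in all. SOX (0.766 ± 0.0109), RUNX (0.730 ± 0.0258), PU.1 (0.7004 ± 0.133), AP-1 (0.662 ± 0.106), POU/OCT (0.606 ± 0.116) and FOX (0.257 ± 0.0467) were below 1, HNF4 stood at 1.19 ± 0.140, and HNF1 had too few matches for a ratio (3 and 2 in the rest of the peaks). Relative to shuffled versions SOX (1.204 and 1.33), RUNX (1.21 and 1.17) and POU/OCT (1.28 and 1.09) lay above 1, as did TEAD (1.29 in both), NKX2-5 (1.45 and 1.197) and HNF4 (1.84 and 1.48). PU.1 (1.29 and 0.879) and GATA (1.14 and 0.794) lay on both sides of 1, and FOX (0.399 and 0.350) and TBX (0.921 and 0.800) stayed below. The CTCF ratio was higher in distal footprints (67.4 ± 15.3) than in promoter footprints (16.8 ± 2.30), and that of ETS was lower (2.24 ± 0.411 and 6.80 ± 2.61). YY1 was higher in distal footprints (8.73 ± 2.25 and 2.59 ± 0.714), and NRF1 (19.2 ± 1.92 and 40.1 ± 15.1) and the cAMP response element (10.7 ± 0.266 and 25.7 ± 2.48) were lower. NFY no longer exceeded 1.5 in distal footprints (1.21 ± 0.0540), nor did the NEUROD E-box (1.37 ± 0.0175) and the MyoD E-box (1.08 ± 0.203) in promoter footprints. ESRR fell to 0.599 ± 0.177 in promoter footprints, and with the stronger 50% of peaks the MyoD E-box had 1.67 and 1.29. The promoter split and the footprints with room for the shift were chosen after seeing the data.

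**Figure D5:**
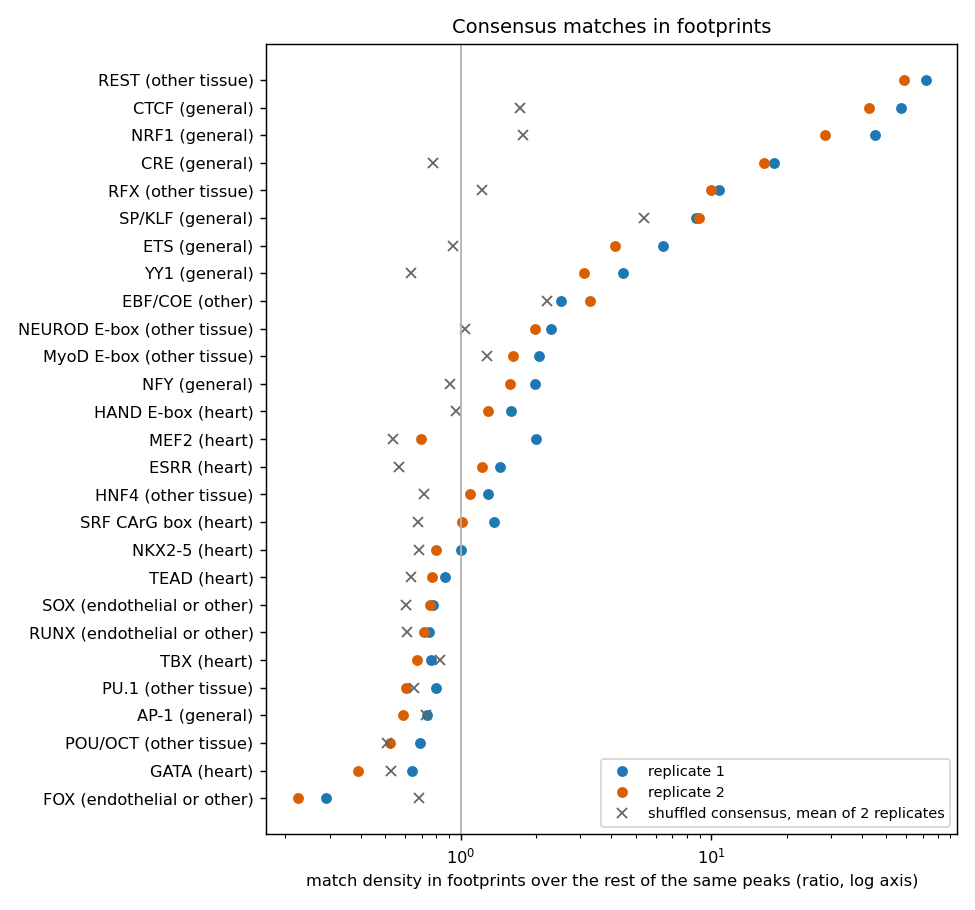
Density of consensus matches in footprints over that in the rest of the same peaks (x axis, ratio, log scale) for 27 consensus sequences (y axis, class in parentheses). Circles are the 2 replicates and crosses the mean over shuffled versions of the consensus, absent for REST. REST and CTCF lie highest, at means of 65.4 and 49.8, and HNF1, with too few matches for a ratio, is not drawn.

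Footprints numbered 594624 in replicate 1 and 547095 in replicate 2, with a median width of 10 and 11 bp. Of these, 64.2% and 63.9% lay inside the library's own peaks, and 89.2% and 91.7% of peaks held at least 1. Between the hearts, 51.3% of the footprints of replicate 1 and 53.3% of those of replicate 2 were shared. Inside peaks the shares were 61.2% and 61.0%, against 41.7% and 43.5% when footprints were moved at random within their peaks. With overlap of at least 50% of each footprint the shares fell to 35.7% and 38.8%.

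The sex chromosomes had few peaks. Chromosome X, present in a single copy in males, held 0.388 of the autosomal number of peaks per Mb in replicate 1 and 0.348 in replicate 2. The mean of 0.368 fell to 0.239 with the stronger 50% of peaks. Chromosome Y held 32 peaks in replicate 1 and 36 in replicate 2, or 0.0068 and 0.0073 of the autosomal rate, and the mean of 0.0070 ranged from 0.0025 with the stronger 50% of peaks to 0.0141 with the longer lists. Y peaks were present in both animals, which the labels give as male.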

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

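The left-out genes with shared promoter windows, the merged peak clusters, the single gene per locus, the promoter footprints and the footprints with room for a shifted window were added after the data were examined, and all other alternatives were planned. No list call turned to the opposite direction under any alternative. Counts of lists above random lists held within 1.5 times for distal peaks (7 to 9 under the alternatives, against 9). For promoters, the counts above and below random lists each moved further under 1 alternative. With a single start site per gene 5 lists were above random promoter lists instead of 9, and with the stronger 50% of peaks 6 were below instead of 3. For single lists, 161 promoter results kept their side of the threshold, 13 lost it and 6 gained it, and for distal peaks 189 kept it and 9 lost it. With genes of shared promoter windows left out, 9 and 3 promoter lists were called, and with peaks under 1 kb apart merged, or 1 gene per locus, 9 distal lists. The share of peaks in common, 79.3% and 76.3%, was 74.6% and 73.4% with the longer peak lists, 86.5% and 83.3% with the stronger 50%, 77.4% and 78.3% with equal numbers of peaks, and 67.04% and 63.8% with overlap of at least 50% of each region. The footprint shares fell to 35.7% and 38.8% under that overlap rule. The rank correlation of 0.904 was 0.908 with that rule, 0.926 as Pearson's r on log2 signal and 0.867 at distal peaks. The promoter share of 23.3% was 18.3% with the longer lists, 33.5% with the stronger 50%, 23.6% with equal numbers, 15.7% within 100 bp and 29.1% within 1000 bp, and 23.1% to 23.5% with each replicate left out. The X ratio of 0.368 fell to 0.239 with the stronger 50%. The Y ratio of 0.0070 was 0.0141 with the longer lists, 0.0025 with the stronger 50% and 0.0057 with equal numbers. The number of consensus sequences with a ratio over 1.5 in both libraries stayed between 9 and 12, against 12, and replicate 1 alone gave 14 and replicate 2 alone 12, while 100 single motif ratios moved by more than 1 SD and 164 did not. Too few background matches left REST, NRF1 and RFX without a ratio for the shifted background, and REST also for promoter footprints and for the stronger 50% of peaks, in at least 1 library. For promoter signals of named genes 481 values stayed within 1 SD and 9 did not. These counts and those of the motif ratios include the settings with a replicate left out, which stay within 1 SD by construction. The SD of promoter signals spans 2 separately normalized libraries and is wide, so these counts do not show stability. The windows and the stronger lists change which peaks count by construction, and for the other shifts the cause was not tested. The planned stronger 50% of footprints was not run, because the deposited score is constant. No paired analysis was possible because the labels give a single group. With 2 libraries, leaving out either one moves a mean by less than 1 SD by construction, which says nothing about stability. At weak peaks, where 34.3% to 43.2% were shared, the absence of a peak in 1 library is not evidence of closed chromatin.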

Other observations

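The tests of the housekeeping promoters, of the signal classes, of classes of similar GC and of the longer lists were chosen after the results they measure were seen. The other tests of GC content and that of repeated words were chosen before. The comparisons of lists between the 2 hearts, with their alternatives by locus, were also made after seeing the data. They set differences between these 2 libraries against random lists and say nothing about animals in general.

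Developmental regulators outside the heart had more distal peaks in replicate 1 than in replicate 2, with 7.86 against 5.18 per gene, while random lists of matched length were higher in replicate 2 by 0.302 on average (adjusted permutation p = 0.0036 over 18 lists). With 1 gene per locus, where windows overlap, the adjusted permutation p was again 0.0036, but without the neighbours Hoxa9 and Hoxa13 the list no longer passed (7 and 5.05, adjusted permutation p = 0.0576). Brain genes had 8.50 against 6.40 (adjusted permutation p = 0.0090), which rested on the neighbours Dlx1 and Dlx2. With 1 gene per locus the adjusted permutation p was 0.110, and without both it was 0.857 (6.67 and 6.56). No other list passed in any of these 3 forms, cardiac transcription factors among them (12.3 and 14.2, adjusted permutation p = 0.118), and no list differed from strength-matched random lists in its promoter signal ratio (lowest adjusted permutation p = 0.112, for cardiac transcription factors). The ratio test held only genes with a promoter peak in both libraries. That left 1 liver, 3 myeloid, 3 lymphoid, 4 erythroid and 4 skeletal muscle genes, so for these lists a missing call says little. Single loci, chosen after their values were seen, showed larger gaps. Within 50 kb of the start site, Dlx1, a forebrain homeobox gene, had 24 distal peaks in replicate 1 and 4 in replicate 2, Foxa1, a factor of endodermal organs, 20 and 1, and Sim1, a hypothalamic factor, 16 and 0. With the longer peak lists the counts were 37 and 9 for Dlx1, 25 and 6 for Foxa1 and 23 and 7 for Sim1, so replicate 2 was not without peaks there. Among genes of the heart, Col1a1 had 44 and 17 and Mybpc3, the cardiac myosin binding protein, 44 and 20. The opposite held at Sik1, a kinase gene, with 15 and 99, at Timp2 with 14 and 49, and at Tnnc1, the cardiac troponin C gene, with 14 and 32. Most of these peaks were weak. At the loci higher in replicate 1 its median signal was 0.301 to 0.494, against 0.785 over all its peaks. In replicate 2 the median was 0.290 at Sik1 and 0.213 at Timp2, against 1.12 over all its peaks, but 1.17 at Tnnc1.

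In the myeloid list the 7 promoters with a peak in replicate 2 alone belonged to C1qa, C1qb, C1qc, Cx3cr1, Fcer1g, Spi1 and Tyrobp, with signals between 0.457 and 1.03, and the 1 with a peak in replicate 1 alone to Adgre1 (0.416). With the longer lists, 11 of 16 were open in replicate 1 and 15 in replicate 2.

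Stretches with many weak distal peaks in a single heart were counted in windows of 20 kb. In 42 windows replicate 1 had at least 10 distal peaks and at least 4 times as many as replicate 2, and in 41 windows the reverse held, while 94 windows had at least 10 in both. The peaks of these windows were weak, with a median signal of 0.284 in the windows of replicate 1 and 0.242 in those of replicate 2. In the longer lists the same windows still had a median of 5.25 times as many peaks in that heart (95% bootstrap interval 4 to 6). The gap was thus not confined to the shorter lists. The cutoffs of both lists are unknown, however, and the longer lists held most peaks of the shorter ones, by which the windows were chosen. A cutoff effect can therefore not be excluded. A GC preference of the libraries may contribute and stays open, since windows of replicate 2 were richer in GC by 3.55 percentage points, with an interval from 0.891 to 5.40 too wide to decide. No biological explanation was tested, since the design gives a single group.

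The higher peak signal of replicate 2 was examined for technical explanations. A single scale factor between the libraries would give the same ratio at all strengths, but the median log2 ratio was higher by 1.11 in the strongest than in the weakest 10% of shared peaks. Different proportions of cell types alone, on a common scale, would leave promoters open in every cell type near 0. Housekeeping promoters had a median log2 ratio of 1.44 (1.29 to 1.58, 20 genes). Their mean of 1.41 was near the 1.45 of random promoters of matched strength, so the value follows the rise with strength. Different proportions are therefore not the only cause on this scale, but a part for them cannot be excluded and stays open. GC content stays open and may account for part of the ratio, which among the strongest peaks rose from 0.97 in the 20% with the lowest GC to 1.65 in the 20% with the highest, and the former decides nothing because its median GC of 54.5% lay above the 41.7% of the genome. Within classes of similar GC the strongest 20% of peaks exceeded the weakest by a median of 0.42 over 10 classes (0.20 to 0.94). This lay between the cutoffs set for GC alone (under 0.2) and for another cause (over 0.5), which were chosen after seeing the data. The bootstrap interval lay above 0 in every class (lowest bound 0.15). Each class still spans a range of GC, however, within which GC can vary with strength. The test therefore cannot decide whether GC of the peaks is the only cause of the rise with strength. A difference in digestion or enrichment stays open, untested, as does any biological difference between the 2 animals.

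The strongest distal peaks are candidates for an artefact of repeated sequence. In the 10 strongest, a median of 76.8% of the 31-base words occurred more than once in the reference, against 0% in 200 other distal peaks. Reads from sequence present in several copies of the reference would give this. None of their words occurred in the mitochondrial genome. The peak in an exon of Cers5, on chromosome 15 at 99735661 to 99736060, had no repeated word and stays open. No biological explanation was tested.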
